A study of Mus musculus with 4 samples.

How the data were processed

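The assay for transposase-accessible chromatin with sequencing (ATAC-seq) was applied to mouse macrophages of 2 genotypes, HO1-KO and WT, with 2 libraries each. HO1 is heme oxygenase-1, the product of the Hmox1 gene. Per the labels' protocols, each library came from 20000 sorted tumor-associated macrophages whose nuclei were treated with Tn5 transposase for 30 minutes at 37 °C, followed by 10 to 12 cycles of PCR. The labels name peripheral blood as the source of the samples while the protocol names tumor-associated macrophages; this difference was not resolved. No label says that the replicates of a genotype came from separate animals, so the spread between them may be technical.

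Per the submitters' processing notes, the tools were Bowtie2, Picard, SAMtools and MACS2, with no versions, and the genome build was mm10. Whether reads were shifted for the Tn5 cut, and how duplicates and multiply mapped reads were treated, is not given in the sources used here. The authors deposited 1 list of called peaks per library, so peaks were called library by library. Each line of the deposited lists holds the position of a summit and its peak, an integer score, the fold of the pileup over the local background, and the −log10 of the p-value and of the q-value. The lowest −log10 q was 1.30 in each of the 4 lists, which corresponds to a threshold of 0.05. The score, the ratio called fold enrichment and the −log10 p-value are the authors' values for each peak. They served to describe, rank and filter peaks within a list, and the fold and −log10 p also gave pileups and background rates, which were compared between libraries and rescaled. Lines that share start and end, being several summits of 1 peak, were counted as 1 peak. Coordinates are 1-based mm10 positions.

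The lists hold no read counts. The fold, taken as (pileup + 1) / (background + 1), and the −log10 p, taken as a Poisson tail, were solved together for the pileup at each summit. Between 99.7% and 99.8% of the summits of a library gave a whole-number pileup within 0.001 of the deposited −log10 p. The lowest background rate per library, which scales with its depth, was 1.97 and 2.50 in the HO1-KO libraries and 2.99 and 3.71 in the WT libraries. Total reads per library were not used here.

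Peaks of the 4 lists were merged into regions wherever they shared at least 1 bp. A region was taken as called in a library when a peak of that library lay in it. Regions called in both WT libraries and neither HO1-KO library are named WT-only, and the reverse HO1-KO-only. These counts were set beside those of the other 2 ways to split the 4 libraries 2 against 2. With 3 splits, an exact permutation test, two-sided, cannot give a p below 0.333. The base-pair Jaccard index is the length shared by 2 lists over the length covered by either. It was computed for the 6 pairs of libraries.

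Genes came from a RefSeq table of assembly GRCm38.p6, which has the coordinates of mm10. That table gives the start and end of each gene without strand or exons. Transcription start sites, promoters, exons and introns were therefore not used here, which departs from the plan. Each region was assigned by its strongest summit to the nearest of 21883 protein-coding genes within 100 kb, with distance 0 inside a gene. Positions were classed as within 1 kb of a gene end, inside a gene farther from its ends, or outside genes. No genome sequence was used here, so the planned test of 17 transcription factor motifs was not run.

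The analysis used 20 gene lists fixed before the data were examined, covering macrophage functions and markers of other cell types; 342 of their 343 genes were in the table. For each list, Fisher's exact test, two-sided, compared the regions of listed genes with those of all other genes. The WT-only test counted WT-only regions among all regions called in both WT libraries, and the HO1-KO-only test used those called in both HO1-KO libraries. Benjamini-Hochberg adjustment covered the 40 tests. Regions are not replicates, so these tests compare 4 peak lists and not the genotypes. Shares carry 95% Wilson intervals, which cover counting error only.

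The genes and regions named were set by rule before the data were examined, with changes made for lack of strand. Gene spans and gene ends replaced start sites, and 10 kb on both sides of Hmox1 replaced 10 kb upstream. Hmox1 came first, with all peaks over it and within 10 kb. Then came the 10 WT-only and 10 HO1-KO-only regions with the highest mean fold over the libraries of that genotype. The 10 genes with the most such regions and the 10 strongest such regions within 1 kb of a gene end followed, per direction. Up to 4 genes per list and direction completed the set. A gene outside this rule is said to be so where it is named.

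The alternatives were −log10 q of at least 5 or 10, lists of equal length (the 35851 strongest peaks of each library by −log10 p), a reciprocal overlap of 50%, summits within 100 bp, and autosomes only. The 2 overlap rules used no merged regions but the peaks of replicate 1 that replicate 2 of the genotype matched. Such a peak was one-sided when no peak of the other genotype met the rule, even where a wider or shifted peak overlapped it. Others were pileups scaled to the background of the shallowest library, each library left out in turn, 2 other gene assignments, strata of peak strength and a replicate block. An equal shortest width, with and without equal length, the B cell list without Ebf1 and a test per gene at equal length were added after the data were seen. The steps were tested on simulated lists. All of 19999 simulated pileups were recovered, as were 3060 of 3060 WT-only and 1530 of 1530 HO1-KO-only regions. These 2 checks cover the arithmetic only: simulated peaks of a region always overlapped, and no difference in depth was simulated. A list of WT-only regions with 3-fold odds was called in 96% of 200 draws. These draws covered the WT-only regions of that list alone. They do not give the sensitivity for shorter lists, for the HO1-KO-only tests or under adjustment over both directions. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.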

Results

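Open chromatin was mapped by ATAC-seq in macrophages of HO1-KO and WT mice, with 2 libraries per genotype. Heme oxygenase-1 breaks heme down to biliverdin, carbon monoxide and iron, and the series title places it upstream of the immunosuppressive program of tumor-associated macrophages. The comparison asks where chromatin was called open in one genotype and not in the other. The data are 4 lists of called peaks. They held 35851 and 37627 peaks in the HO1-KO libraries and 43580 and 50799 in the WT libraries. The mean was 36739 ± 1256 (SD, n = 2) in HO1-KO and 47190 ± 5105 (SD, n = 2) in WT. Peaks covered 23.5 and 24.7 Mb in HO1-KO and 29.7 and 34.7 Mb in WT. The background rate, which follows depth, was also lower in both HO1-KO libraries, at 1.97 and 2.50 against 2.99 and 3.71. Depth and genotype were therefore confounded. With 2 libraries against 2, the exact permutation test gave its smallest possible p, 0.333.

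Hmox1, the targeted gene, lies on chromosome 8 from 75093618 to 75100593 (mm10). The region over its lower-coordinate end, 75093249 to 75094025, was called in all 4 libraries. Its peaks had a fold over background of 6.50 and 7.27 in the HO1-KO libraries and 7.55 and 7.06 in the WT libraries. Regions at 75083621 to 75084228, 75089295 to 75090093 and 75108679 to 75109915 were also called in all 4 libraries. The region at 75086014 to 75086548 was called in HO1-KO replicate 2 and in both WT libraries. The region at 75101319 to 75101701, which starts 726 bp beyond the higher-coordinate end of the gene, was called in both HO1-KO libraries and in neither WT library, with folds of 3.86 and 3.43. This call was weak, with a pileup of 13 in each HO1-KO library and −log10 q of 3.85 and 3.15, under the alternative threshold of 5. No library had a peak in the rest of the gene span, so these lists neither show nor exclude a deletion there and do not check the labels.

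**Figure D1:**
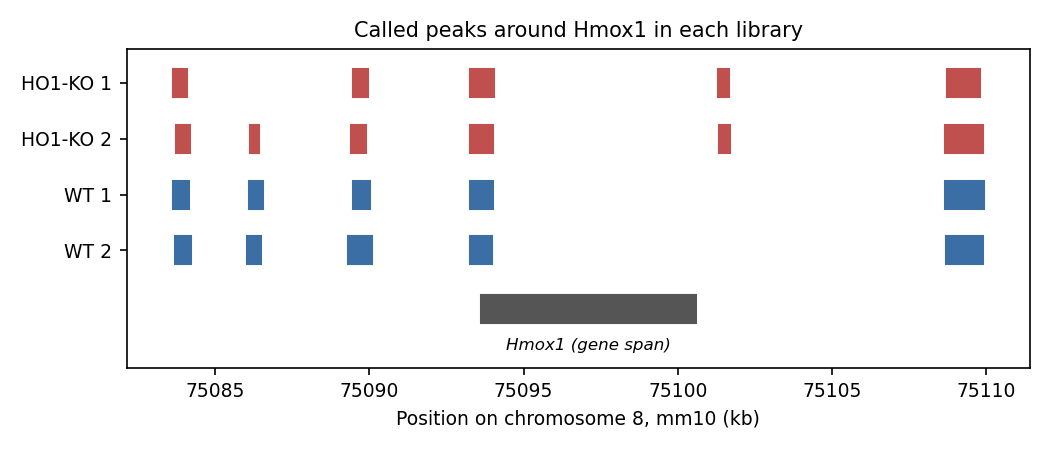
Called peaks around Hmox1 on chromosome 8 (mm10, kb on the horizontal axis), 1 row per library, red for HO1-KO and blue for WT, with the gene span as a grey bar. The region at 75093249 to 75094025 was called in all 4 libraries. The region at 75101319 to 75101701 was called in the HO1-KO libraries only, with −log10 q of 3.85 and 3.15.

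The 4 lists merged into 57544 regions, of which 28490 were called in all 4 libraries. WT-only regions numbered 5305 and lay near 3626 genes. The strongest were at Nedd4l, a ubiquitin ligase gene (chromosome 18, 65119758 to 65119996, mean fold 38.0), and at 2 places with no protein-coding gene within 100 kb, on chromosome 12 from 3109871 to 3110112 (mean fold 34.8) and from 93576984 to 93577227 (mean fold 22.7). These 3 regions were 239, 242 and 244 bp wide. The narrowest peak reported was 248 and 245 bp wide in the HO1-KO libraries and 236 and 228 bp wide in the WT libraries, so these regions were narrower than any peak listed for HO1-KO. Next came regions on chromosome 13 from 102386847 to 102387135 (mean fold 10.9), in Coa5, an assembly factor of cytochrome c oxidase (chromosome 1, 37419494 to 37419991, 10.7), and in Synpo2, which encodes an actin-binding protein (chromosome 3, 123216592 to 123217135, 10.7). Regions near Lamp2, a lysosomal membrane protein gene, and S100a11, a calcium-binding protein gene, had mean folds of 10.1 and 9.87. The region inside Flt1, which encodes VEGF receptor 1, had a mean fold of 9.51 (chromosome 5, 147659809 to 147660290). A further one lay on chromosome 2 from 84094599 to 84095137 (9.77).

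Of the WT-only regions, 386 lay within 1 kb of a gene end. Ms4a7, a tetraspan gene of macrophages, had one at 11321111 to 11321468 on chromosome 19 (mean fold 6.82). Cd200r4, of the CD200 receptor family, had one at 44811312 to 44812274 on chromosome 16 (6.74), and Clec12b, a C-type lectin receptor gene, one at 129427385 to 129427743 on chromosome 6 (6.31). The strongest of this class was at Pgpep1 (chromosome 8, 70645374 to 70646522, 7.98). The others were at Xkr5, Kcng2, Cmpk1, Zfp558, Kank3 and Abca6, with mean folds between 6.42 and 7.14. Genes with the most WT-only regions were Thada, with 8 of its 20 regions called in both WT libraries, and Ubash3b, Asap1 and Arsb with 7 each. Arsb encodes a lysosomal sulfatase. Tbxas1, the gene of thromboxane synthase, had 6 of 18, and Rptor, which encodes the mTORC1 subunit raptor, also 6 of 18. Mtss1, Lpp, Susd6 and the Y-linked Gm52481 had 6 each. With lists of equal length, the WT-only regions were 4 for Thada, 3 each for Ubash3b, Arsb and Susd6, 1 each for Asap1 and Rptor, 5 each for Mtss1 and Lpp, and 6 each for Tbxas1 and Gm52481.

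HO1-KO-only regions numbered 675 and lay near 526 genes. The strongest was at Dynlt1b, a dynein light chain gene (chromosome 17, 6429742 to 6431214, mean fold 9.15), with another nearby at 6476518 to 6477489 nearest to Gm2808 (8.14). Genes of the Dynlt1 family lie there in near-identical copies, so the placement of reads there is uncertain. Others were in Lrp11 (chromosome 10, 7608617 to 7609162, 8.80) and near Sec24b, which encodes a coat protein of COPII vesicles (chromosome 3, 130090172 to 130090932, 8.18). Further regions were nearest to Marveld2, a tight junction gene, Myoz2, a muscle Z-disc gene, Kctd3, Slc2a10, a glucose transporter gene, Bdkrb2, the bradykinin B2 receptor gene, and Cnot2, with mean folds between 6.53 and 7.49. Within 1 kb of a gene end, HO1-KO-only regions lay at Irs1, the gene of insulin receptor substrate 1 (chromosome 1, 82291280 to 82291776, mean fold 5.24), Lat, a T cell receptor adaptor gene (chromosome 7, 126369207 to 126369887, 4.94), and Lipe, the hormone-sensitive lipase gene (chromosome 7, 25379701 to 25380155, 4.61). The Dynlt1b region also belongs to this class and was its strongest. The remaining ones were at Xlr3b, Bmp2k, Slc30a4, Hmgcll1 and Defb33 and inside Fyco1, with mean folds between 4.56 and 5.83. The region inside Fyco1 (chromosome 9, 123806075 to 123806653) lay 31 bp from an end of another gene and far from the ends of Fyco1 (123789500 and 123851899). The most HO1-KO-only regions lay near Gm52481 and 9530057J20Rik, with 4 each. Dlgap1, Tenm4, Pde4d, Celf2 and Mid1 had 3 each. Myoz2, Mdm1 and Zfp281 had 2 each and were taken by mean fold among ties, as Ebf1, Sorcs2 and Pls3 also had 2. Counts were not scaled to gene length. Pde4d spans 1302 kb, with 3 of 26 regions, and Dlgap1, Tenm4 and Celf2 span 740 to 857 kb. With lists of equal length, Dlgap1 and Tenm4 had 5 each, Mid1 4, Gm52481, Pde4d, Celf2 and Myoz2 3 each, and 9530057J20Rik, Mdm1 and Zfp281 2 each.

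The genotype split held 5980 one-sided regions, against 1482 when libraries were split by replicate number and 1259 when the numbers were crossed. WT-only regions exceeded HO1-KO-only regions 7.86-fold. At equal list length the counts were 2013 and 1752, or 3765 in all against 1251 and 1200 in the other splits. Equal length itself pulls the 2 sides together, and it drops weaker WT peaks, so a HO1-KO-only region there may still have had a WT peak in the deposited lists. The q thresholds drop weaker peaks as well. A region one-sided at −log10 q of at least 5 or 10 may thus have had a peak of the other genotype in the deposited lists. At an equal shortest width, 7 of the 10 strongest WT-only regions remained. At −log10 q of at least 10, the 10 regions named near gene ends came down to 7 for WT-only and 2 for HO1-KO-only, and 8 of the 10 strongest HO1-KO-only regions remained. The HO1-KO-only count moved more than 1.5-fold with −log10 q of at least 5 (297) or 10 (99), reciprocal overlap (1435) and summits within 100 bp (1349). The counts of the 2 overlap rules are peaks of HO1-KO replicate 1 that no WT peak matched under the rule, and a WT peak may still overlap them. Leaving out a library removes a condition and raises the counts. Without WT replicate 1 the WT-only count was 13079 and without HO1-KO replicate 2 it was 8855, while HO1-KO-only regions numbered 2473 without HO1-KO replicate 1, 2071 without HO1-KO replicate 2 and 1528 without WT replicate 2.

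**Figure D2:**
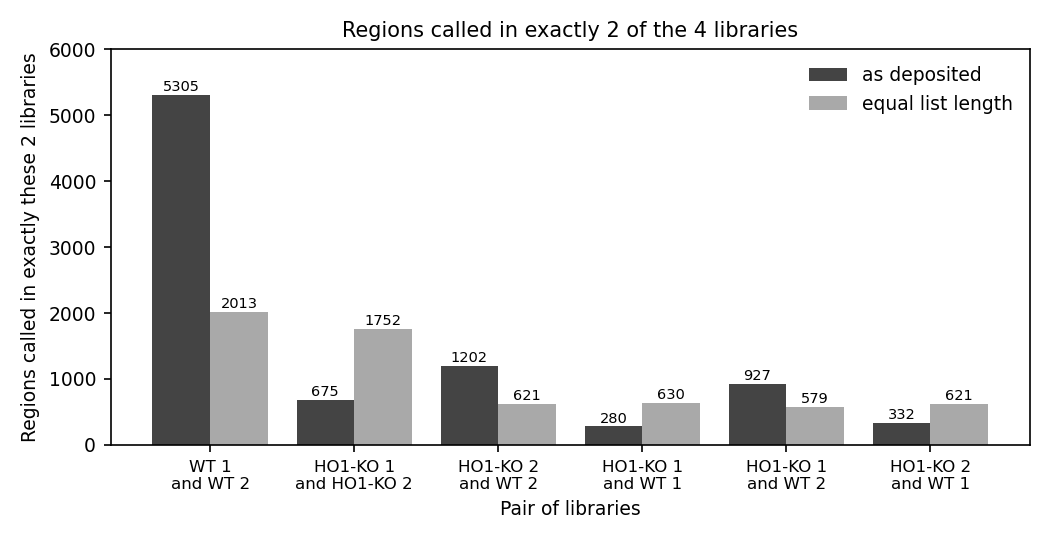
Number of regions called in exactly 2 of the 4 libraries (vertical axis), for each pair of libraries, in the lists as deposited (dark bars) and with 35851 peaks per library (light bars). The pairs of one genotype held 2013 and 1752 regions at equal list length, and the mixed pairs between 579 and 630.

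Libraries of one genotype shared more of their called bases than libraries of different genotypes. The Jaccard index was 0.651 for the HO1-KO pair and 0.687 for the WT pair, and lay between 0.573 and 0.629 for the 4 mixed pairs. The mean within genotypes exceeded the mean between them by 0.0671, whereas the other 2 splits gave -0.0320 and -0.0351. At equal list length the HO1-KO pair had 0.656 and the WT pair 0.725, and the mixed pairs lay between 0.619 and 0.649. The genotype split ranked first of 3, the exact permutation p being 0.333, the smallest these libraries allow.

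A smaller share of one-sided regions than of shared ones lay near gene ends, with intervals that did not overlap. Of the WT-only regions, 7.28% (95% Wilson interval 6.61 to 8.01) had their strongest summit within 1 kb of a gene end, as had 6.37% (4.76 to 8.47) of the HO1-KO-only regions and 32.5% (31.9 to 33.0) of those called in all 4 libraries. Regions inside genes farther from their ends made up 50.4% of the WT-only set, 41.3% of the HO1-KO-only set and 36.2% of the regions in all 4. One-sided regions were also weaker than shared ones within the same lists. Their median fold was 3.90 against 6.68 for WT and 3.94 against 6.59 for HO1-KO. Near 176 genes, both WT-only and HO1-KO-only regions were found. The share near gene ends reached 11.0% for WT-only regions at −log10 q of at least 10 and 21.6% for HO1-KO-only regions with summits within 100 bp, against 44.5% and 34.0% for regions in all 4. Under the summit rule a HO1-KO-only peak may still overlap a WT peak with a shifted summit.

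In the deposited lists of peaks, none of the 20 gene lists differed from other genes in its share of WT-only regions after Benjamini-Hochberg adjustment of Fisher's exact test. The lowest adjusted p was 0.763. One list had an unadjusted p under 0.05, the housekeeping controls, with 1 of 43 regions (2.33%, interval 0.412 to 12.1, exact p = 0.0382), near Actb. With summits within 100 bp this share was 13.5%, against 17.3% over all regions called in both WT libraries. Among regions of all other genes the share in the deposited lists was about 13.2%. Macrophage identity genes had 19 WT-only regions among 110 (17.3%, interval 11.3 to 25.4), near 12 of 22 genes. They included 3 near Spi1, which encodes the macrophage master regulator PU.1, and 2 each near Maf, Mertk, an efferocytosis receptor gene, and Itgam, the gene of CD11b. Heme and iron genes had 8 among 76 (10.5%, interval 5.43 to 19.4). Aco1, which encodes iron regulatory protein 1, and Lrp1, the hemopexin receptor gene, had 2 each, and Tfrc, the transferrin receptor gene, and Bach1, the heme-binding repressor of Hmox1, had 1 each. NRF2 and antioxidant genes had 7 among 71 (9.86%, interval 4.86 to 19.0), with 3 near Nfe2l2, the gene of NRF2 itself, and 1 each near Slc7a11, G6pdx and Gclc. For −log10 q of at least 5 the NRF2 share was 3.17% of 63 regions (Fisher's exact p = 0.00969, adjusted p = 0.0969), against 14.2% over all regions. The shares at equal list length were 9.09% (macrophage identity), 6.35% (heme and iron) and 3.17% (NRF2), against about 6.24% for other genes, with 1 region each near Spi1 and Nfe2l2.

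Immunosuppressive and alternative activation genes had 12 WT-only regions among 126 (9.52%, interval 5.53 to 15.9). This share moved with the setting, at 23.9% for −log10 q of at least 10 (Fisher's exact p = 0.0580, adjusted p = 0.434) and 3.88% at equal list length. Over all regions called in both WT libraries the share moved too, from 13.3% as deposited to 16.4% and 6.36%. It was 15.8% with reciprocal overlap and 17.3% with summits within 100 bp. Part of the shifts given here is therefore common to all regions. Mmp9 and the scavenger receptor gene Msr1 had 2 each, and Stat3 and Pdcd1lg2, the gene of PD-L2, had 1 each. Inflammatory genes had 12 among 131 (9.16%, interval 5.32 to 15.3), with 2 each near Tlr2, Irf1 and Cd86 and 1 near Irf5. Their share was 20.5% for −log10 q of at least 10 and 4.50% at equal list length. Interferon response genes had 3 among 56 (5.36%), namely 2 near Ifih1 and 1 near Ifngr1, and a share of 11.3% with reciprocal overlap. Antigen presentation genes had 8 among 58 (13.8%), with 2 each near Nlrc5 and Cd1d1 and 1 each near Ciita, the master regulator of MHC class II, and Psmb9. Their share was 20.9% of 43 regions for −log10 q of at least 5 (Fisher's exact p = 0.189) and 21.2% of 33 for at least 10 (exact p = 0.474). The interferon and antigen presentation lists each had a share of 2.27% at equal list length, where Ifih1, Ifngr1, Nlrc5, Cd1d1, Ciita and Psmb9 had 0 WT-only regions. Migration, angiogenesis and matrix genes had 22 among 137 (16.1%, interval 10.9 to 23.1), near 16 of 23 genes, with 2 each near Flt1, Ccr1, Itgav and Nrp2. Their share was 26.7% with summits within 100 bp (Fisher's exact p = 0.00886, adjusted p = 0.257), 25% for −log10 q of at least 10 (exact p = 0.0419, adjusted p = 0.419) and 9.26% at equal list length. AP-1 and immediate early genes had 14 among 119 (11.8%), with 3 each near Ier3, Nr4a1 and Klf6 and 1 near Jun. Lipid and lysosome genes had 14 among 117 (12.0%), with 3 each near Lgmn and the cholesterol exporter gene Abca1, 2 near Fabp5 and 1 near Lpl, and a share of 6.73% at equal list length.

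The markers of other cell types held few regions. WT-only regions were 2 of 22 for T cells (9.09%), 2 of 18 for NK cells (11.1%), 2 of 9 for B cells (22.2%, both near Cd22), 3 of 18 for neutrophils (16.7%) and 4 of 34 for dendritic cells (11.8%). They were 2 of 7 for fibroblasts (28.6%), 7 of 32 for endothelium (21.9%, with 2 each near Cdh5, Vwf and Erg), 5 of 21 for epithelium (23.8%, with 2 near Cdh1) and 1 of 4 for erythroid cells (25%, near Epor). No share in this group passed the test in the deposited lists. Epithelial markers passed at −log10 q of at least 5, with 58.3% of 12 regions (Fisher's exact adjusted p = 0.0180). HO1-KO peaks under that threshold were not counted, so some of these regions may have had a HO1-KO peak in the deposited lists. The epithelial share was 80% of 5 regions at −log10 q of at least 10 (exact adjusted p = 0.118) and 0% of 10 regions at equal list length. T cell markers had 40% of 20 regions with summits within 100 bp (Fisher's exact p = 0.0129, adjusted p = 0.257) and 50% of 8 for −log10 q of at least 10 (exact p = 0.0274, adjusted p = 0.366). Over all regions the share was 17.3% and 16.4% in these settings, 14.2% at −log10 q of at least 5 and 6.36% at equal list length. With lists of equal length the shares were 0% for NK cells, B cells and erythroid cells, 4% for dendritic cells, 7.69% for neutrophils and 13.0% for endothelium. With 1 library left out, WT-only shares with an unadjusted p under 0.05 were 47.6% of 21 for epithelium without HO1-KO replicate 2 (exact p = 0.0136, adjusted p = 0.136) and, without WT replicate 2, 2.27% of 44 for housekeeping (exact p = 0.00275, adjusted p = 0.0551), 7.02% of 57 for interferon (exact p = 0.0360) and 41.7% of 12 for B cells (exact p = 0.0481).

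**Figure D3:**
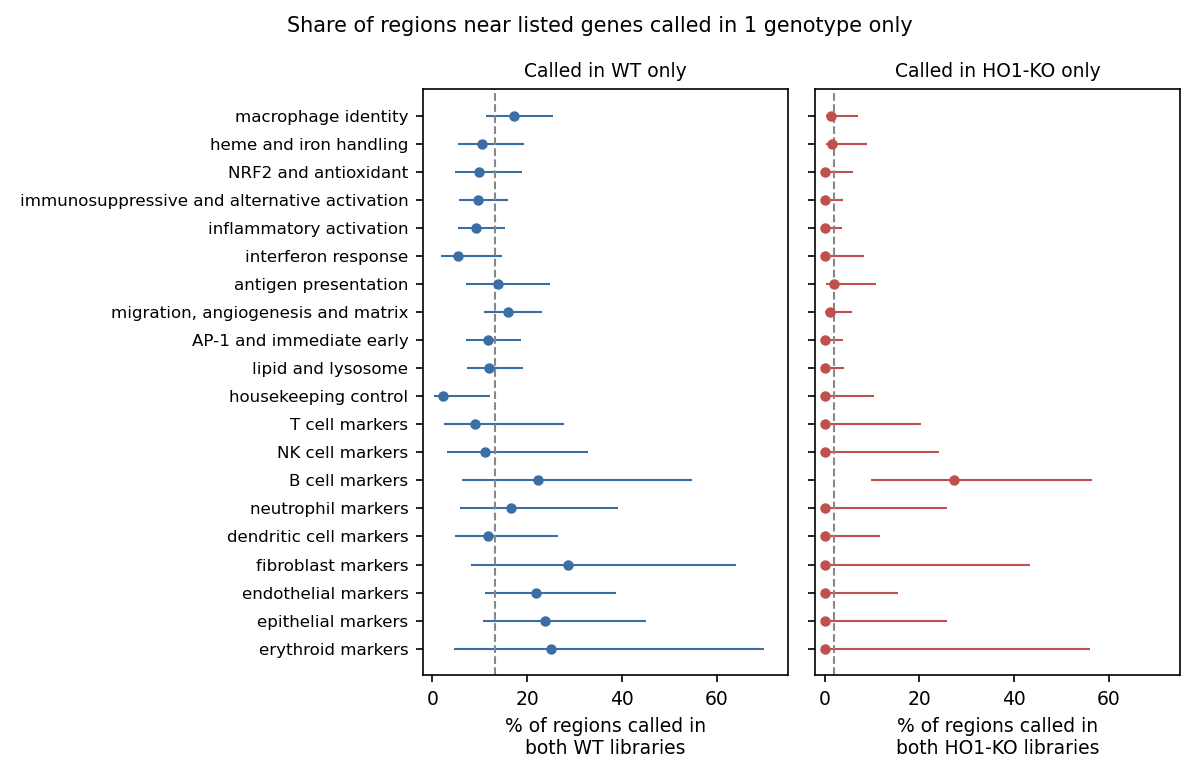
Share of regions (%, horizontal axis) near the genes of each list that were WT-only, of regions called in both WT libraries (left, blue), or HO1-KO-only, of regions called in both HO1-KO libraries (right, red). Bars are 95% Wilson intervals and dashed lines the median share among all other genes; the B cell markers on the right, at 27.3%, are the list past the adjusted threshold.

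One list, the B cell markers, had a higher share of HO1-KO-only regions than other genes. Of its 11 regions called in both HO1-KO libraries, 3 were HO1-KO-only (27.3%, interval 9.75 to 56.6), against 2.00% for other genes (odds ratio 18.4, Fisher's exact adjusted p = 0.0471). Ebf1, a transcription factor gene of the B lineage, had 2 of them, on chromosome 11 from 44950399 to 44950791 (mean fold 5.46) and from 44764409 to 44765306 (3.37). The gene of the B cell kinase Blk had 1, on chromosome 14 from 63416955 to 63417331 (3.95). The number of B cell marker regions per library was 15 and 13 in HO1-KO and 12 and 13 in WT. Without Ebf1 the call was lost, with an adjusted p of 0.888. It was also lost without WT replicate 1, with summits within 100 bp (Fisher's exact adjusted p = 1), and with the nearest gene end within 25 kb (0.972). At −log10 q of at least 10, 0 of the 2 remaining regions of the list were HO1-KO-only, which is too few regions to judge the call. The call held at −log10 q of at least 5 (Fisher's exact adjusted p = 0.0246, 2 of 5 regions) and with reciprocal overlap (0.0374, 4 of 10 regions). At equal list length 5 of 10 regions were HO1-KO-only (Fisher's exact adjusted p = 0.00398).

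In the deposited lists no other list passed the test for HO1-KO-only regions or had an unadjusted p under 0.05. Dendritic cell markers, with 0 of 29 there, passed at −log10 q of at least 5, with 12.5% of 24 regions (Fisher's exact adjusted p = 0.0317). None of their regions was HO1-KO-only as deposited, so WT peaks that fell under that threshold may account for this call. Dendritic cell markers had 5 of 29 at equal list length (17.2%, Fisher's exact p = 0.0196, adjusted p = 0.393), where the same limit holds. Unadjusted p was also under 0.05 for antigen presentation at −log10 q of at least 5 (6.45% of 31 regions, exact p = 0.0472), epithelial markers at 10 or more (50% of 2, exact p = 0.0105) and inflammatory genes with reciprocal overlap (0% of 89, exact p = 0.0230), with adjusted p of 0.352, 0.210 and 0.459. With 1 library left out it was under 0.05 for lipid and lysosome genes (0% of 103 without HO1-KO replicate 1, exact p = 0.00298, adjusted p = 0.0595) and, without HO1-KO replicate 2, for inflammatory genes (0% of 110, exact p = 0.00455), endothelial markers (20% of 30, exact p = 0.00452), both with an adjusted p of 0.0607, and AP-1 genes (0.990% of 101, exact p = 0.0451). The same held for immunosuppressive genes without HO1-KO replicate 1 (0.885% of 113, exact p = 0.0157) or WT replicate 2 (0% of 95, exact p = 0.0235), and for epithelial markers without HO1-KO replicate 1 (19.0% of 21, exact p = 0.0362). HO1-KO-only regions near genes of these lists were 1 each near Hmox1 itself, Lyz2, the lysozyme gene of myeloid cells, H2-DMb2, which serves peptide loading of MHC class II, and Fn1, the fibronectin gene. The immunosuppressive list had 0 among 95 regions (interval to 3.89%), the inflammatory list 0 among 98 (to 3.77%), the AP-1 list 0 among 93 (to 3.97%), the lipid and lysosome list 0 among 91 (to 4.05%), the NRF2 list 0 among 61 (to 5.92%) and the interferon list 0 among 42 (to 8.38%). The housekeeping, T cell, NK cell, neutrophil, dendritic cell, fibroblast, endothelial, epithelial and erythroid lists, of 3 to 33 regions each, also had 0. The immunosuppressive share was 6.90% of 87 regions with summits within 100 bp (Fisher's exact p = 0.454) and 5.31% of 113 without HO1-KO replicate 2. That of lipid and lysosome genes was 6.74% of 89 with reciprocal overlap (exact p = 0.452). All lay above these limits. The share over all regions called in both HO1-KO libraries rose as well, from 2.23% to 5.27% (summits) and 5.05% (reciprocal overlap). Leaving out HO1-KO replicate 2 also raised the count over all regions. Intervals this wide leave room for shares above the 2.00% of other genes.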

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

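The shortest width alternatives and the B cell list without Ebf1 were chosen after the data were seen. With −log10 q of at least 5, HO1-KO-only regions numbered 297, 1 list passed for WT-only regions (epithelial markers) and 2 for HO1-KO-only regions (B cells, dendritic cells), and the shares near a gene end were 8.07% (WT-only), 9.76% (HO1-KO-only) and 37.2% (all 4 libraries). With at least 10, the values in the same order were 99 regions, 0 lists for HO1-KO-only regions, and 11.0%, 11.1% and 44.5%. The B cell odds ratio was 0 there, from 0 of 2 regions. Equal length gave 2013 WT-only and 1752 HO1-KO-only regions and shares of 5.66%, 9.82% and 34.1%; with an equal shortest width too these were 1966 and 1716 and 5.60%, 9.79% and 34.1%. Reciprocal overlap gave 1435 HO1-KO-only regions and 8.44%, 12.7% and 34.8%, and summits within 100 bp gave 1349 regions, 0 lists and 10.7%, 21.6% and 34.0%. Under these 2 rules the regions are peaks of replicate 1, and those called one-sided may still overlap a peak of the other genotype. Leaving out 1 library at a time gave 7762 to 13079 WT-only and 883 to 2473 HO1-KO-only regions, and 0 to 1 lists for HO1-KO-only regions. Fewer libraries to satisfy raise such counts by construction. Of the regions called in all remaining libraries, 29.8% to 32.4% lay near a gene end. The nearest gene end within 25 kb, and the B cell list without Ebf1, left 0 lists. B cell odds ratios that no longer passed were 3.76 (summits), 13.8 (without WT replicate 1), 8.46 (25 kb) and 6.98 (without Ebf1). Apart from the list's construction without Ebf1, the cause of these changes was not tested. The WT-only count stayed within 1.5-fold of 5305 under the 2 q thresholds, both overlap rules, autosomes, scaled pileups and equal width, and the Jaccard difference stayed positive, from 0.0308 without WT replicate 2 to 0.0958. A replicate block, counting regions called in 1 genotype within each replicate number, gave 2 lists for WT-only and 8 for HO1-KO-only regions. No label used here says whether the numbers pair the libraries. Deviations of same-numbered libraries had a correlation of -0.000766 over regions, which shows no shared deviation in the calls but cannot exclude a pairing. Of the main results' values 69 stayed and 43 moved; of the others 628 stayed within their interval or side, 105 moved, 4 lost their call and 1 reversed. Motif tests were not run, and Jaccard has no value under the 2 other overlap rules. Peaks near the threshold in the shallower HO1-KO libraries limit what can be called absent there.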

Other observations

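The tests per gene at equal list length, and those of list length, linked strain DNA, sex, batch, regrouping and Lyz2 were chosen after the result was seen. At equal list length, Ank3, the gene of ankyrin-G, which anchors membrane proteins to the spectrin skeleton, had 6 HO1-KO-only regions among 8 (Fisher's exact adjusted p = 0.00889). It was the 1 gene past the threshold among 12802 tested, of which 134 had an unadjusted p under 0.05. Tead1, a transcription factor gene of the Hippo pathway, had 4 of 4 (Fisher's exact adjusted p = 0.0582), and Tenm4 had 5 of 10 (0.236). In the deposited lists the HO1-KO-only regions were 1 of 8 for Ank3, 1 of 4 for Tead1 and 3 of 11 for Tenm4. For WT-only regions 0 of 12753 genes passed and 121 had an unadjusted p under 0.05. Btbd16 had 4 of 7 and Tbxas1 6 of 18 WT-only regions there.

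Gm52481 on chromosome Y was among the genes with the most regions in both directions, with 6 WT-only and 4 HO1-KO-only regions in the deposited lists. Placement of reads there was not checked. Peaks on Y numbered 35 and 30 in the HO1-KO libraries and 30 and 36 in the WT libraries.

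WT-only regions outnumbered HO1-KO-only regions, 5305 against 675. Leaving out peaks narrower than 248 bp removed 9.75% of the WT-only count, leaving 4788 against 721, which argues against the shortest reported width as the main source. List length may contribute: in the 2 splits that mix genotypes, the pair with the longer lists held 4.29 and 2.79 times as many one-sided regions as the other pair, with 88426 against 79431 and 86650 against 81207 peaks. With pileups scaled to the shallowest library the ratio was 4.75, but read depth and genotype cannot be told apart: scaling the deeper library of a pair left it with 1.33% (HO1-KO) and 13.6% (WT) more peaks than the other within a genotype, and with 12.7% to 28.1% more between genotypes. A difference in accessibility between the genotypes stays open beside depth.

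At equal list length the genotype split held 3765 one-sided regions, and the highest of the other splits 1251; 1 of the 3 splits reached the real count, and 3 splits are too few for a share under 0.05. Strain DNA linked to the targeted locus would enrich chromosome 8, whose share of one-sided regions was 1.13 times its share of regions called in at least 2 libraries, with 36 of 3765 within 10 Mb of Hmox1. A sex that differs by genotype would leave 1 genotype without peaks at Y genes, but of the 4 genes Ddx3y, Eif2s3y, Kdm5d and Uty each library had a peak at 3 or more. The labels give a batch for 0 libraries, so a preparation batch shared by genotype cannot be told apart from the genotype. Equal list length does not equalize depth. Both HO1-KO libraries were shallower, with background rates of 1.97 and 2.50 against 2.99 and 3.71 in WT. The genotype split is thus also a split by depth, and the 2 cannot be told apart here. An effect of HO1 loss on chromatin is a hypothesis that these lists leave open.

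The region at the higher-coordinate end of Lyz2 (chromosome 10, 117281906 to 117282440), chosen after its values were seen, was called in both WT libraries, with folds of 4.14 and 4.52, and in neither HO1-KO library. Scaled to the shallowest library, the weaker WT peak kept a −log10 p of 9.72, against a lowest called value of 3.35 there, which argues against read depth alone. The scaling is approximate, as over all peaks it left WT replicate 2 with 13.6% more peaks than WT replicate 1. Toward Lyz1, 2 of 2 neighbouring regions (117284912 to 117285550 and 117288116 to 117288725) were called in all 4 libraries, with −log10 p of at least 8.03. On the other side 117277735 to 117278066 was called in WT replicate 2 only (−log10 p 6.48). The region 117275486 to 117276311 was called in both WT libraries only (4.78 and 3.48), and 117274771 to 117275234 in both HO1-KO libraries only (3.43 and 5.38). These calls were weak, so missing calls there may reflect the threshold. A candidate explanation is a change at the Lyz2 locus itself, such as the Cre gene inserted there in a widely used macrophage deleter strain, which may stop reads from mapping across the insertion. The labels name no Cre strain, and peak lists cannot show inserted sequence, so this and a lower accessibility of Lyz2 in HO1-KO cells cannot be told apart.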
